A study of Mus musculus with 2 samples.

How the data were processed

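Retinas of 2 mouse genotypes on the C57BLKS background were profiled by droplet single-cell RNA sequencing at 13 weeks of age. One genotype carried the wild-type leptin receptor gene Lepr, and the other was homozygous for the db mutation of that gene (db/db), an obese and diabetic mouse model. Per the labels, retinas of both eyes were taken from 2 mice per genotype, dissociated with enzymes and made into 10x Genomics 3' v3.1 libraries. Each genotype had 1 library, and no map from cells to mice was used here.

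The authors counted unique molecular identifiers (UMIs) per gene and cell barcode. The deposited values were raw counts from 10x Genomics cellranger 6.0.1, per the file headers. Cell Ranger and the mm10 mouse genome were named in the submitters' processing notes. The annotation release, the rule that separated cells from empty droplets and the use of read strand in counting were not given in the sources used here. The matrices held 32285 genes, with 10308 barcodes in the wild-type library and 11083 in the db/db library. The labels gave about 6000 cells loaded and about 3000 targeted per library, fewer than the barcodes in either matrix. The lowest UMI count of a barcode was 508 in the wild-type library and 500 in the db/db library. Positions were taken by gene identifier from the GENCODE M21 annotation of GRCm38, which held 32235 of the 32285 genes.

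Cells with at least 200 detected genes and at most 20% of UMIs from mitochondrial genes were kept. The gene minimum removed 1 wild-type and 7 db/db barcodes, and the mitochondrial limit concerned 77 and 113. Doublets were scored with Scrublet in scanpy 1.11.5, separately in each library. The caller marked 0 wild-type cells and 1 db/db cell, or 0% and 0.009%, which is too few for a caller that worked at this loading. Doublets therefore largely stayed in the data, and an alternative left out the 8% of cells with the highest doublet scores, 825 and 887 cells. The 10230 wild-type and 10962 db/db cells that remained held 35524110 and 33544268 UMIs.

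Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen over both libraries, were scaled and reduced to 40 principal components. Cells were joined to 15 neighbours and clustered with the Leiden method at a resolution of 1.0, both libraries together and without integration. Clusters were named from marker genes fixed in advance. A name required at least 3 markers of the class at 2 times the level in other classes or more. A cluster stayed unnamed if its 10 leading genes held more markers of another class than of its own. Cells outside the rod clusters were then clustered again on their own, a step chosen after seeing the data. Clusters that were named rod in that second round were set apart as mixed with rod. Classes with at least 50 cells in each library were compared within the class, namely rod-like, cone-like, bipolar-like, Muller glia-like and microglia or macrophage-like cells.

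With 1 library per genotype no test between genotypes was possible, and none of the differences has a replicate check. Cells are not replicates. Shares of cells have exact Clopper-Pearson intervals, summed UMIs exact Poisson intervals, and ratios exact conditional binomial intervals, all at 95%. These intervals cover counting error only, and leave out differences between mice and between dissociations. UMIs were summed per library and class and scaled to a class total of 1000000, the unit abbreviated as CPM. The log2 ratio is db/db to wild type, so that a positive value means a higher level in the db/db library. A count of 0 was set to 3 UMIs in a ratio. Genes with at least 50 UMIs in a class over both libraries counted as measured.

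Genes were named by a fixed rule. It took, in each class, measured genes whose CPM in the library with the higher level was at least 0.5 times that over all kept cells. Mitochondrial, ribosomal protein and haemoglobin genes were left out, as were gene models named Gm or Rik and, outside rods, rod markers. The listed sex-linked genes Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty were left out too, but other genes of the X chromosome were not. The remaining genes were ranked by the interval bound nearest 0, and the 6 highest and 6 lowest were named, or 3 and 3 in microglia or macrophage-like cells. Genes that differed by a log2 ratio of at least 1 in the same direction in at least 4 classes were named as well, together with Lepr, the sex-linked genes and up to 4 members of each described gene list. Some genes and 1 list that the rules cover are not reported here.

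Gene lists for retinal cell types, stress, immune and metabolic pathways were fixed in advance, and 34 of them had at least 5 measured members in at least 1 class. Each list is given as the median log2 ratio of its measured members, and as the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. A list is called outside the random range when its median lay outside the central 95% of the random medians. Intervals of list medians were obtained by redrawing Poisson counts. The list of ribosomal proteins followed a naming rule that also takes in Rps27rt and Rps19bp1. The insulin, IGF and leptin signalling list holds Pdk1, a pyruvate dehydrogenase kinase gene that is also in the hypoxia response list.

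The ratio and list scripts were tested on simulated counts drawn from the real class means and library sizes. The simulated changes also shift the class total, and this shift was allowed for in the expected ratios. On that basis log2 ratios of 1 were recovered with a median of 1.003 over 48 such genes among 12005 in rod-like cells. In microglia or macrophage-like cells the median was 1.10 over 45 among 1517. The intervals covered 93.8% and 91.1% of these ratios. Of 100 unchanged lists per class, from 1 to 4 lay outside the random range, and a list simulated with a log2 ratio of 1 lay at percentile 100 in each compared class.

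The alternatives concerned the cell filters, doublets, scaling within each library before clustering, clustering resolution, the denominator of shares, TMM scaling in edgeR 4.0.16, other totals for scaling, subtraction of free RNA, equal weight per cell, other UMI minimums and thinning of each cell to 1000 UMIs. Free RNA was taken as the all-cell profile of each library and subtracted from classes other than rod at an upper estimate of its amount. The groups, the markers, the gene lists, the naming rule, the comparisons and these alternatives were fixed before the data were examined. A single round of clustering, leaving out 1 bipolar, 1 rod or 1 Muller glia cluster, keeping 1 of the 2 microglia clusters found at a resolution of 2.0, and leaving out list members on another chromosome were added after the data were seen. Leaving out clusters with over 90% of cells from 1 library was planned, and no such cluster was found. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.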

Results

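Single-cell RNA sequencing was performed on retinas of wild-type and db/db mice at 13 weeks of age, to compare the cell classes of the retina and their expression in diabetic and control animals. Each genotype was represented by 1 library made from 2 mice. The labels also describe the control mice as m/m. The wild-type library held 35642274 UMIs over 10308 barcodes and the db/db library 33742189 UMIs over 11083 barcodes. Kept cells had a median of 2314 UMIs and 1258 genes in the wild-type library, and of 2051 UMIs and 1152 genes in the db/db library. After thinning to 1000 UMIs per cell, which left 8338 and 9573 cells, the medians were 693 and 695 genes. No difference between the libraries has a replicate check, and all intervals are 95% intervals for counting error only.

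Lepr (ENSMUSG00000057722; GRCm38 chromosome 4, 101717404 to 101815352, plus strand), which encodes the leptin receptor, was detected at 6 UMIs in each library, with an interval of 2.20 to 13.1 UMIs. The db mutation alters splicing of the long receptor isoform, so a 3' tag count checks nothing about the mutation or the labels. Leprot, which lies upstream of Lepr on the same strand, had 633 UMIs in the wild-type and 657 in the db/db library. As a library check, the Y-linked gene Ddx3y had 4693 and 3832 UMIs and Xist, expressed from the inactive X chromosome, 8 and 5 UMIs in the wild-type and db/db libraries. The other Y-linked genes Eif2s3y, Uty and Kdm5d had 5025, 1893 and 1294 UMIs in the wild-type library and 5003, 1785 and 1242 in the db/db library.

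Rod-like cells made up a larger share of the db/db library, and the inner retinal classes smaller shares. Rod-like cells accounted for 81.0% of kept wild-type cells (80.2 to 81.7%) and 87.0% of kept db/db cells (86.3 to 87.6%). Amacrine-like cells, inhibitory interneurons, were at 1.11% (0.920 to 1.34%) in the wild-type and 0.274% (0.185 to 0.390%) in the db/db library, a ratio of 0.246 (0.159 to 0.370). Muller glia-like cells, the radial glia of the retina, were at 1.81% (1.56 to 2.09%) and 0.821% (0.661 to 1.01%), a ratio of 0.454 (0.349 to 0.587). Bipolar-like cells, which relay photoreceptor signals, were at 6.58% (6.11 to 7.08%) and 4.47% (4.09 to 4.87%), a ratio of 0.680 (0.604 to 0.765).

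Cone-like cells formed 4.13% (3.75 to 4.53%) of the wild-type and 3.33% (3.0 to 3.68%) of the db/db library, a ratio of 0.807 (0.700 to 0.931). Among cells that were not rod-like the direction for cones turned, with 21.7% (19.9 to 23.6%) of 1948 wild-type and 25.5% (23.3 to 27.9%) of 1430 db/db cells, a ratio of 1.18 (1.02 to 1.36). With that denominator bipolar-like cells were at 34.5% and 34.3%, a ratio of 0.992 (0.881 to 1.12). Muller glia-like cells were at 9.50% and 6.29% and amacrine-like cells at 5.85% and 2.10% of cells that were not rod-like, ratios of 0.663 (0.509 to 0.857) and 0.358 (0.231 to 0.540). Microglia or macrophage-like cells were at 0.616% (0.473 to 0.787%) and 0.547% (0.418 to 0.704%) of kept cells, within counting error of each other, with a ratio of 0.889 (0.614 to 1.29) that was 1.30 (0.896 to 1.88) among cells that were not rod-like. Cells resembling retinal pigment epithelium were at 0.450% (0.329 to 0.599%) and 0.146% (0.0835 to 0.237%), and erythroid-like cells at 0.235% (0.150 to 0.349%) and 0.365% (0.261 to 0.497%). Among cells that were not rod-like their ratios were 0.474 (0.250 to 0.853) and 2.27 (1.34 to 3.94), against 0.325 (0.172 to 0.584) and 1.56 (0.915 to 2.70) over all kept cells, so that the erythroid ratio was beyond counting error with the first denominator alone. Cells mixed with rod, with a median of 6222 UMIs in the wild-type and 4176.5 in the db/db library, formed 3.78% and 2.96% of kept cells, or 19.9% and 22.7% of cells that were not rod-like. A small cluster led by Kirrel3, Pcdh7 and Adarb2 stayed unnamed, at 0.332% and 0.137%.

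Shares depend on how each retina was dissociated and on the droplets called as cells, and the UMI minimum of about 500 per barcode bears on small cells. Both amacrine-like clusters held fewer db/db cells. The cluster led by Cartpt and Gad1 held 52 wild-type and 9 db/db cells, and the cluster led by Snhg11 and Tfap2b held 62 and 21. In the main clustering no cluster was named as ganglion, horizontal, endothelial or pericyte-like cells, which does not show that such cells were absent. Under 4 alternatives a cluster with Snhg11 and Tfap2b among its leading genes was named horizontal, with 56 wild-type and 18 db/db cells where at least 500 genes per cell were required. Scaling within each library gave a ganglion-like cluster of 18 and 23 cells.

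**Figure D1:**
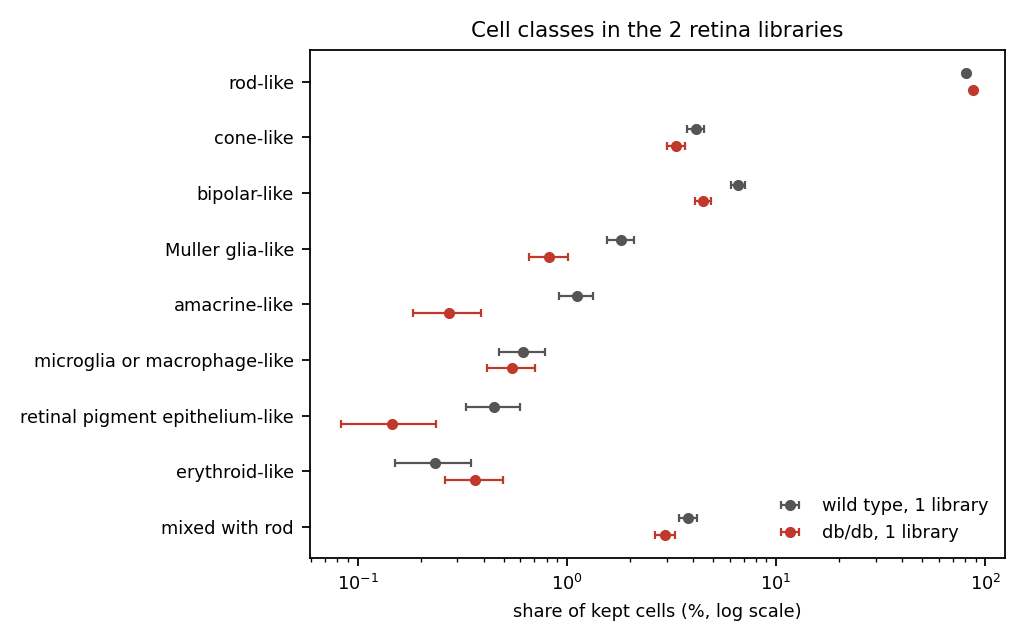
Share of kept cells per class (%, log axis) in the wild-type (grey) and db/db (red) libraries, 1 library each, with 95% Clopper-Pearson intervals for counting error only. Rod-like cells were at 81.0% and 87.0%, and amacrine-like cells showed the lowest ratio among the classes, 1.11% against 0.274%.

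In rod-like cells of the db/db library, Selenbp1, encoding the selenium-binding enzyme methanethiol oxidase, was 4.93-fold higher, and the gene model AC149090.1 was 4.60-fold higher. BC065403, an antisense transcript, and Cxcl12, a chemokine gene, were also among the genes named by rule as higher, with low counts. Ribosomal protein genes and nuclear-encoded genes of the respiratory chain were lower as groups by small amounts, and hypoxia response genes were slightly higher. The rod phototransduction genes differed little as a group. These values rest on 8282 wild-type and 9532 db/db cells with 25583883 and 26644291 UMIs, and different rod clusters held the most cells, a cluster with 22.8% of wild-type rods in the one and a cluster of low mitochondrial share with 20.6% of db/db rods in the other.

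Selenbp1 (ENSMUSG00000068874; chromosome 3, 94933056 to 94944758) had 122 UMIs in wild-type and 626 in db/db rod-like cells, a log2 ratio of 2.30 (2.02 to 2.59). AC149090.1 (ENSMUSG00000095041), a protein-coding gene model on the unplaced scaffold JH584304.1, had 533 and 2552 UMIs, a log2 ratio of 2.20 (2.07 to 2.34). BC065403 (ENSMUSG00000097211; chromosome 9, 72361735 to 72409945, minus strand) had 18 and 234 UMIs, a log2 ratio of 3.64 (2.95 to 4.42). Its count is uncertain, because antisense genes can be told from their partners only where strand is used in counting. Mns1, a gene of motile cilia and sperm flagella on the same chromosome (72438011 to 72462025), was higher with a log2 ratio of 1.81 (1.45 to 2.18). Shisa2, encoding an endoplasmic reticulum protein, was higher with a log2 ratio of 1.65 (1.44 to 1.86). Cxcl12 had 6 and 97 UMIs, a log2 ratio of 3.96 (2.78 to 5.44), which was 0.96 among cells with at least 500 genes, 0.97 among cells with at most 10% mitochondrial UMIs and 1.55 after thinning.

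Lower in rod-like cells of the db/db library were Palmd, encoding palmdelphin, with 63 and 7 UMIs and a log2 ratio of -3.23 (-4.60 to -2.10), and Pls3, an actin-bundling protein gene, with -1.74 (-2.29 to -1.21). Zfp69 had -1.54 (-2.21 to -0.90), the phosphoglucomutase gene Pgm2 -1.49 (-2.11 to -0.91), Eps8l1 -1.19 (-1.46 to -0.91) and Dnah9, an axonemal dynein gene, -1.12 (-1.36 to -0.89). The ratio of Palmd was -5.94 among cells with at most 10% mitochondrial UMIs.

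Of 31 lists described in rod-like cells, 2 were above the random range and 13 below it. Hypoxia response genes had a median of 0.15 (0.10 to 0.18) at percentile 99.9, with 10 of 12 members higher, among them Pdk1, a kinase that restrains pyruvate dehydrogenase (0.56), Vegfa, the vascular growth factor gene (0.25), and Ankrd37 (0.21). Fatty acid oxidation and PPAR targets had a median of 0.13 (-0.01 to 0.16) at percentile 97.8, with 11 of 18 members higher, among them Fabp3 (0.48) and Acaa2 (0.41), while Plin2 was at -0.42, and the median was 0.00 after thinning. Cytosolic ribosomal proteins had a median of -0.22 (-0.23 to -0.21) with 78 of 80 members lower, among them Rpsa (-0.38) and Rps4x (-0.34). Nuclear-encoded respiratory genes had a median of -0.12 (-0.13 to -0.11) with 41 of 47 members lower, including Ndufa13 (-0.25) and Atp5h (-0.21), and -0.05 with equal weight per cell. Heat shock genes were at -0.11 (-0.16 to -0.07) with 10 of 11 lower, led by Hsph1 (-0.50). Unfolded protein response genes were at -0.09 (-0.17 to -0.05) with 14 of 17 lower, led by Asns (-0.64) and Hsp90b1 (-0.47), while Dnajb9 was at 0.35. Antioxidant enzymes were at -0.11 (-0.17 to -0.07) with 10 of 12 lower, led by Prdx2 (-0.24), and -0.04 after thinning. Apoptosis genes had a median of -0.07 (-0.09 to 0.04) but a mean of 0.01, with Cdkn1a at 0.57 and Bcl2l11 at 0.28. Inflammatory genes were at -0.46 (-0.79 to 0.08) over only 5 measured members, with Ccl4 at -1.59 and Nfkbia, an inhibitor of NF-kB, at 0.32.

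Genes of other cell classes were also lower in rod-like cells of the db/db library, which held smaller shares of cone, bipolar and Muller glia-like cells. Cone phototransduction genes had a median of -0.21 (-0.26 to -0.16), with Arr3 at -0.54 and Opn1mw at -0.41. Bipolar ON signalling genes were at -0.22 (-0.30 to -0.03) and rod bipolar genes at -0.24 (-0.51 to -0.03), with Gpr179 at -1.21 and Trpm1 at -0.83. The bipolar ON median was -0.04 over members with at least 200 UMIs. Muller homeostasis genes were at -0.23 (-0.42 to -0.17), with Gpr37 at -0.92 and Crym at -0.68, and Muller gliosis genes at -0.20 (-0.33 to 0.11), with Vim at -0.51, Cp at -0.49 and Edn2 at 0.38. The Muller gliosis median was 0.10 over members with at least 200 UMIs and -0.01 after thinning. The activated microglia list was at -0.20 (-0.23 to -0.17), with Cd9 at -0.49 and Apoe at -0.48, while the shares of microglia or macrophage-like cells were within counting error of each other.

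The other 16 lists in rod-like cells lay within the random range, with medians from -0.09 to 0.08. Among them were rod phototransduction genes at -0.01 (-0.02 to 0.00), glycolysis genes at 0.03 with a mean of -0.01, immediate early genes at 0.01 with a mean of -0.14 (Fosb at -1.36, Egr1 at -0.94 and Rhob at 0.51), mitochondrial-encoded respiratory genes at -0.09, cholesterol synthesis genes at 0.08, circadian clock genes at 0.08, and insulin, IGF and leptin signalling genes at 0.05. Glucose-responsive genes had a median of -0.03 and a mean of 0.05, and MHC class I and II genes a median of -0.08 and a mean of 0.04. Angiogenic and vascular factors were at -0.03. The 5 RNA-quality transcripts had a median of -0.01 and a mean of -0.38, with Snhg11 at -1.29, Meg3 at -0.73 and Malat1 at 0.08.

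In cone-like cells of the db/db library Selenbp1 was again among the genes with the highest ratios, and glycolysis genes and mitochondrial-encoded respiratory genes were higher as groups. Hypoxia response genes had a median below 0 in cone-like cells (-0.22), which was -0.04 after free RNA was subtracted and -0.05 without the mitochondrial filter. Genes of the polyol, hexosamine and glyoxalase pathways, which handle excess glucose and its by-products, had the highest list median in this class. The comparison covered 422 wild-type and 365 db/db cells with 1854750 and 1590034 UMIs.

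Selenbp1 had 16 and 70 UMIs in cone-like cells, a log2 ratio of 2.35 (1.55 to 3.23), and AC149090.1 had 97 and 213, a log2 ratio of 1.36 (1.0 to 1.72). Also higher were Rxra, encoding retinoid X receptor alpha (1.67, from 0.79 to 2.63), Slc19a1, the reduced folate carrier gene (1.39, from 0.60 to 2.23), Agr2, a protein disulfide isomerase gene (1.24, from 0.72 to 1.77), and Tmsb15b1, a thymosin gene (1.22, from 0.65 to 1.82). Lower were Acsl5, an acyl-CoA synthetase gene (-1.51, from -2.41 to -0.68), the kinesin gene Kif4 (-1.40, from -2.15 to -0.71), Vkorc1l1, a vitamin K epoxide reductase gene (-1.40, from -2.08 to -0.76), Zfhx3 (-1.36, from -2.22 to -0.57), the helicase gene Ddx10 (-1.28, from -2.14 to -0.48) and the immediate early gene Fosb (-0.98, from -1.43 to -0.53). Most of these genes had under 100 UMIs per library. A single round of clustering gave 0.55 for Rxra, 0.60 for Slc19a1 and -0.61 for Vkorc1l1, and thinning gave 0.44 for Tmsb15b1, -0.58 for Kif4 and -0.29 for Ddx10.

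Of 23 lists in cone-like cells, 5 were above and 3 below the random range. Glycolysis genes had a median of 0.15 (0.09 to 0.19) at percentile 99.99, with 18 of 19 members higher, among them the glucose transporter gene Slc2a1 (0.51), Pfkp (0.44) and Gpi1 (0.42). The polyol, hexosamine and glyoxalase list had a median of 0.27 (0.12 to 0.41) with 7 of 8 members higher, led by Fn3k (0.57), Oga (0.54) and Khk (0.41), and 0.10 with a single round of clustering. Mitochondrial-encoded respiratory genes were at 0.19 (0.15 to 0.21) with 9 of 13 higher, such as mt-Co3 (0.30), and 0.08 among cells with at most 10% mitochondrial UMIs. Nuclear-encoded respiratory genes were at 0.05 (0.02 to 0.08) with 32 of 47 higher, such as Ndufa2 (0.26), but 0.00 without the mitochondrial filter. Circadian clock genes were at 0.16 (0.01 to 0.25) with 11 of 15 higher, including Tef (0.38) and Per3 (0.32), while Per1 was at -0.78 and Rorb at -0.32. Hypoxia response genes were at -0.22 (-0.35 to -0.02) with 7 of 10 lower, among them Kdm3a (-0.62) and Ndrg1 (-0.40), while Mxi1 was at 0.40.

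Rod phototransduction genes in cone-like cells had a median of -0.19 (-0.24 to -0.16), with Gnat1 at -0.43. The list holds genes that cones also express, such as Grk1 and Guca1a, which are in the cone list too. Its median was 0.01 without the 8% of cells with the highest doublet scores and 0.06 after free RNA was subtracted. Cytosolic ribosomal proteins were at -0.05 (-0.07 to -0.02) with 56 of 80 lower, among them Rpl18 (-0.23), and 0.01 at a clustering resolution of 2.0. The other 15 lists had medians from -0.14 to 0.12, among them cone phototransduction genes at 0.01 (-0.03 to 0.07), immediate early genes at -0.09, the unfolded protein response at -0.07, heat shock genes at -0.07, and apoptosis genes at 0.08 with a mean of -0.03. Muller homeostasis genes were at 0.03 with a mean of -0.09.

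In bipolar-like cells of the db/db library immediate early genes, the transcription factors and signalling genes that respond first to stimulation, were lower, with Fosb 5.24-fold lower. Tacr3, the neurokinin 3 receptor gene expressed in some OFF bipolar types, had the lowest ratio among the named genes. Mitochondrial-encoded respiratory genes were higher, and genes of rod bipolar cells and of ON signalling were lower by small amounts in sums over the class. The comparison covered 673 wild-type and 490 db/db cells with 2115269 and 1595052 UMIs.

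Tacr3 had 79 and 8 UMIs, a log2 ratio of -2.90 (-4.16 to -1.85), and Fosb had 139 and 20, a log2 ratio of -2.39 (-3.14 to -1.71). AC149090.1 had 539 and 1017 UMIs, a log2 ratio of 1.32 (1.17 to 1.48). Also higher were Nxph3, a neurexophilin gene (1.38, from 0.67 to 2.12), Slc16a7, the monocarboxylate transporter 2 gene (1.12, from 0.72 to 1.53), Cacna2d2, a calcium channel subunit gene (1.11, from 0.83 to 1.38), Kcnip4, a potassium channel-interacting protein gene (0.98, from 0.62 to 1.34), and the transcription factor gene Nfib (0.88, from 0.62 to 1.15). Ebf1 (-1.87), Nxph1 (-1.61), Neto1 (-1.41) and Slit2 (-1.13) were also named as lower. These 4 genes are among the leading genes of a bipolar cluster of 31 wild-type and 6 db/db cells, or 4.61% and 1.22% of the class. Without it the log2 ratios were 0.34 for Ebf1, 1.92 for Nxph1 and 1.14 for Neto1, whereas Slit2, which also led a bipolar cluster of 31 wild-type and 16 db/db cells, stayed lower at -0.81. Another bipolar cluster, led by Grik1 and Gsg1, held 11.9% of wild-type and 20.6% of db/db bipolar-like cells.

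Of 27 lists in bipolar-like cells, 2 were above and 6 below the random range. Immediate early genes had a median of -0.55 (-0.70 to -0.29), below each of the 10000 random lists, with 10 of 14 members lower, among them Fosb, Fos (-0.95), Jun (-0.84) and Atf3 (-0.79). This median was -0.33 among cells with at most 10% mitochondrial UMIs. Unfolded protein response genes were at -0.22 (-0.31 to -0.13) with 12 of 14 lower, including Dnajb9 (-0.62), Asns (-0.42) and Sesn2 (-0.36), while Xbp1 was at 0.41, and the median was -0.06 after thinning. Mitochondrial-encoded respiratory genes were at 0.18 (0.15 to 0.25) with 11 of 13 higher, led by mt-Co3 (0.41) and mt-Co1 (0.38), and 0.07 among cells with at most 10% mitochondrial UMIs. Hypoxia response genes were at 0.12 (-0.01 to 0.22) with 9 of 12 higher, led by Pdk1 (0.30), and 0.03 without the highest doublet scores. Rod bipolar genes were at -0.21 (-0.31 to -0.13) with 7 of 8 lower, and ON signalling genes at -0.17 (-0.22 to -0.10) with 11 of 14 lower. Both lists hold Prkca (-0.40), the protein kinase C alpha gene, and Pcp2 (-0.25), and the ON list holds the channel gene Trpm1 (-0.29). A single round of clustering gave -0.08 for the ON list. The class sums pool bipolar clusters whose shares differ, such as the cluster led by Grik1 and Gsg1 (11.9% of wild-type and 20.6% of db/db cells). Lower levels within cells were not told apart from a different mix. Nuclear-encoded respiratory genes were at -0.07 (-0.10 to -0.04) with 33 of 47 lower, such as Ndufs7 (-0.22), and ribosomal proteins at -0.09 (-0.11 to -0.07) with 68 of 80 lower, such as Rps20 (-0.31). The other 19 lists had medians from -0.12 to 0.13, among them cone bipolar genes at -0.11 (-0.30 to 0.12), glycolysis genes at 0.04, synaptic genes at -0.03, apoptosis genes at 0.07 with a mean of -0.03, and circadian clock genes at 0.05 with a mean of -0.07.

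Muller glia-like cells of the db/db library had lower levels of interferon response, immediate early and heat shock genes. Higher in these cells were Anxa1, encoding the annexin A1 protein with known anti-inflammatory actions, and Ndufa4l2, a gene known to be induced by hypoxia. The homeostatic genes of Muller glia and the gliosis genes, by contrast, lay within the random range as groups. The comparison covered 185 wild-type and 90 db/db cells with 1215057 and 623254 UMIs, all in 1 cluster whose leading genes Ccn1 and Zfp36l1 are known to respond to stimulation. At a clustering resolution of 2.0 the class also held a cluster of 30 wild-type and 4 db/db cells, or 16.2% and 4.44% of the class, with the endothelial genes Flt1 and Kdr among its leading genes. Without these cells the interferon response median was -1.01, the immediate early median -0.42 and the log2 ratio of Gbp7 -3.66.

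Anxa1 had 16 and 75 UMIs, a log2 ratio of 3.19 (2.40 to 4.07), and Ndufa4l2 had 8 and 44, a log2 ratio of 3.42 (2.32 to 4.72). The LIM domain gene Crip1 was at 1.31 (0.98 to 1.65) and AC149090.1 at 0.88 (0.60 to 1.15). Psat1, a gene of serine synthesis, was at 0.98 (0.54 to 1.41), but at -0.12 after thinning. Gbp7, a guanylate-binding protein gene known to be induced by interferon, had 49 and 2 UMIs, a log2 ratio of -3.65 (-6.74 to -1.72). Over the alternatives its log2 ratio was from 0.601 to 1.018 times this value. G0s2, an inhibitor of triglyceride lipase, had 80 and 8 UMIs, a log2 ratio of -2.36 (-3.62 to -1.31), and -1.02 after thinning. The other genes named as lower were Snhg11 (-2.66), Scgn (-2.62), Trpm1 (-2.13) and Gng13 (-1.92). These are genes of amacrine or bipolar cells, classes with smaller shares in the db/db library. Without the highest doublet scores, Scgn was at -0.85 and Trpm1 at -1.202. Over the alternatives the log2 ratio was from 0.599 to 1.106 times the main value for Snhg11, and from 0.927 to 2.121 times for Gng13.

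Of 30 lists in Muller glia-like cells, 7 were below and 0 above the random range. The interferon response had a median of -1.02 (-1.40 to -0.79) with 9 of 10 members lower, among them Ifit3 (-2.07), Isg15 (-1.91), Xaf1 (-1.51) and Irf9 (-1.25), and -1.56 after thinning. Immediate early genes were at -0.39 (-0.44 to -0.35) with 16 of 17 lower, including Atf3 (-0.90), Nr4a1 (-0.81), Klf6 (-0.68) and Rhob (-0.58). Heat shock genes were at -0.39 (-0.48 to -0.27) with 8 of 10 lower, led by Dnajb1 (-0.97) and Hspa1a (-0.97). RNA-quality transcripts were at -0.44 (-0.56 to -0.16) with 4 of 5 lower, among them Snhg11, Neat1 (-0.44) and Meg3 (-0.44). Cone phototransduction genes were at -1.19 (-1.61 to -0.92) with Pde6h at -3.52 and Arr3 at -2.12, bipolar ON genes at -0.42 (-1.01 to -0.18) with Pcp2 at -1.75, and synaptic genes at -0.14 (-0.29 to -0.01) with Cplx3 at -1.41. These 3 lists were fixed as genes of photoreceptors or neurons. The cone list was at -0.02 and the synaptic list at 0.16 without the highest doublet scores, and the cone list was at 1.01 after free RNA was subtracted.

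The other 23 lists in Muller glia-like cells had medians from -0.12 to 0.16. Muller homeostasis genes were at 0.02 (-0.05 to 0.07), Muller gliosis genes at -0.05 (-0.23 to 0.03), glycolysis genes at 0.05, and angiogenic and vascular factors at 0.16 (0.02 to 0.28) at percentile 91.8. Hypoxia response genes were at 0.16 and fatty acid oxidation and PPAR targets at 0.13. The mean differed in sign from the median for inflammatory genes (-0.43 against 0.00), MHC class I and II genes (-0.04 against 0.10) and mitochondrial-encoded respiratory genes (-0.01 against 0.03).

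Microglia or macrophage-like cells, the immune cells of the retina, had the widest ratios among the named genes of the compared classes. Apoe, the apolipoprotein E gene, was 10.9-fold higher in the db/db library, and Lyz2, the lysozyme gene of macrophages and other myeloid cells, was 9.34-fold higher. MHC class II genes, which present antigen, and the chemokine gene Ccl5 were lower, with Ccl5 at 100 UMIs in the wild-type and 5 in the db/db library. Immediate early genes were higher, while they were lower in bipolar-like and Muller glia-like cells, a difference between classes that was not tested. The class had 63 wild-type and 60 db/db cells in 1 cluster, led by the chemokine genes Ccl4 and Ccl3, with median depths of 1968 and 4342.5 UMIs. Under 5 alternatives it split into a deep cluster led by Ccl4 and Ccl3 and a shallow one with C1qb, Tyrobp and Cd74 among its leading genes. With at least 500 genes per cell these held 26 wild-type and 34 db/db cells, and 21 and 12 cells.

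Apoe had 231 and 3107 UMIs in microglia or macrophage-like cells, a log2 ratio of 3.44 (3.25 to 3.64). Lyz2 had 30 and 347, a log2 ratio of 3.22 (2.68 to 3.81), and 2.06 after thinning. Aqp4, the water channel gene of Muller glia, had 2 and 69 UMIs, a log2 ratio of 4.80 (2.89 to 7.87), but 1.08 with equal weight per cell. After thinning Aqp4 had too few UMIs for a ratio, since the wild-type cells held only 2 before it. Ccl5 had a log2 ratio of -4.63 (-6.28 to -3.36), and the MHC class II genes H2-Eb1 and H2-Aa had -4.12 (-5.47 to -3.02) and -3.81 (-4.91 to -2.87). With equal weight per cell these 3 ratios were -1.96, -1.66 and -1.38, and among cells with at least 500 genes H2-Eb1 was at -6.96 and H2-Aa at -7.18. In the deep and the shallow cluster found at a resolution of 2.0, H2-Aa was at -6.08 and -2.76 and Lyz2 at 3.51 and 1.66. Markers of Muller glia summed to 366 UMIs in wild-type and 3737 in db/db cells of the class, or to 135 and 630 without Apoe. Markers of B cells, which also carry MHC class II, summed to 38 and 21 UMIs, those of granulocytes to 30 and 34, and those of T or NK cells to 0 and 40.

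Of 17 lists in microglia or macrophage-like cells, 4 were above and 5 below the random range. MHC class I and II genes had a median of -1.10 (-1.45 to -0.97) with 8 of 8 members lower, including H2-Ab1 (-2.60) and Cd74 (-1.63). Immediate early genes were at 0.51 (0.42 to 0.58) with 17 of 17 higher, led by Klf4 (1.59), Fos (1.08), Fosb (0.98) and Klf2 (0.96). Metallothioneins and NRF2 targets were at 0.39 (0.26 to 0.50) with 6 of 8 higher, led by Srxn1 (1.06) and Mt1 (1.0). Muller gliosis genes were at 0.62 (0.25 to 0.97) with 4 of 6 higher, among them Cebpb (1.63), Socs3 (1.12) and Vim (1.01), genes that immune cells also express, while Ccl2 was at -0.74. Cytosolic ribosomal proteins were at 0.22 (0.18 to 0.25) with 74 of 78 higher, such as Rpl31 (0.77), but -0.03 after thinning. Heat shock genes were at -0.46 (-0.62 to -0.24) with 8 of 10 lower, among them Hspa8 (-0.73) and Hsp90ab1 (-0.56). Nuclear-encoded respiratory genes were at -0.27 (-0.41 to -0.12) with 23 of 31 lower, such as Ndufs7 (-1.10), and -0.09 with equal weight per cell. Rod phototransduction genes were at -0.47 (-0.58 to -0.37) with Pde6g at -1.01, and synaptic genes at -0.54 (-0.81 to -0.25) with Unc13b at -1.13. Both lists were fixed as genes of photoreceptors or neurons.

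The other 8 lists had medians from -0.27 to 0.20 in microglia or macrophage-like cells. Homeostatic microglial genes were at 0.20 (0.01 to 0.30) at percentile 92.5, with 7 of 10 higher. Activated microglia genes had a median of -0.06 but a mean of 0.40, and inflammatory genes a median of 0.07 and a mean of -0.12. The median was -0.14 and the mean 0.25 for insulin, IGF and leptin signalling. Complement genes were at -0.16 and glycolysis genes at -0.27 (-0.50 to -0.14) at percentile 5.12.

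**Figure D2:**
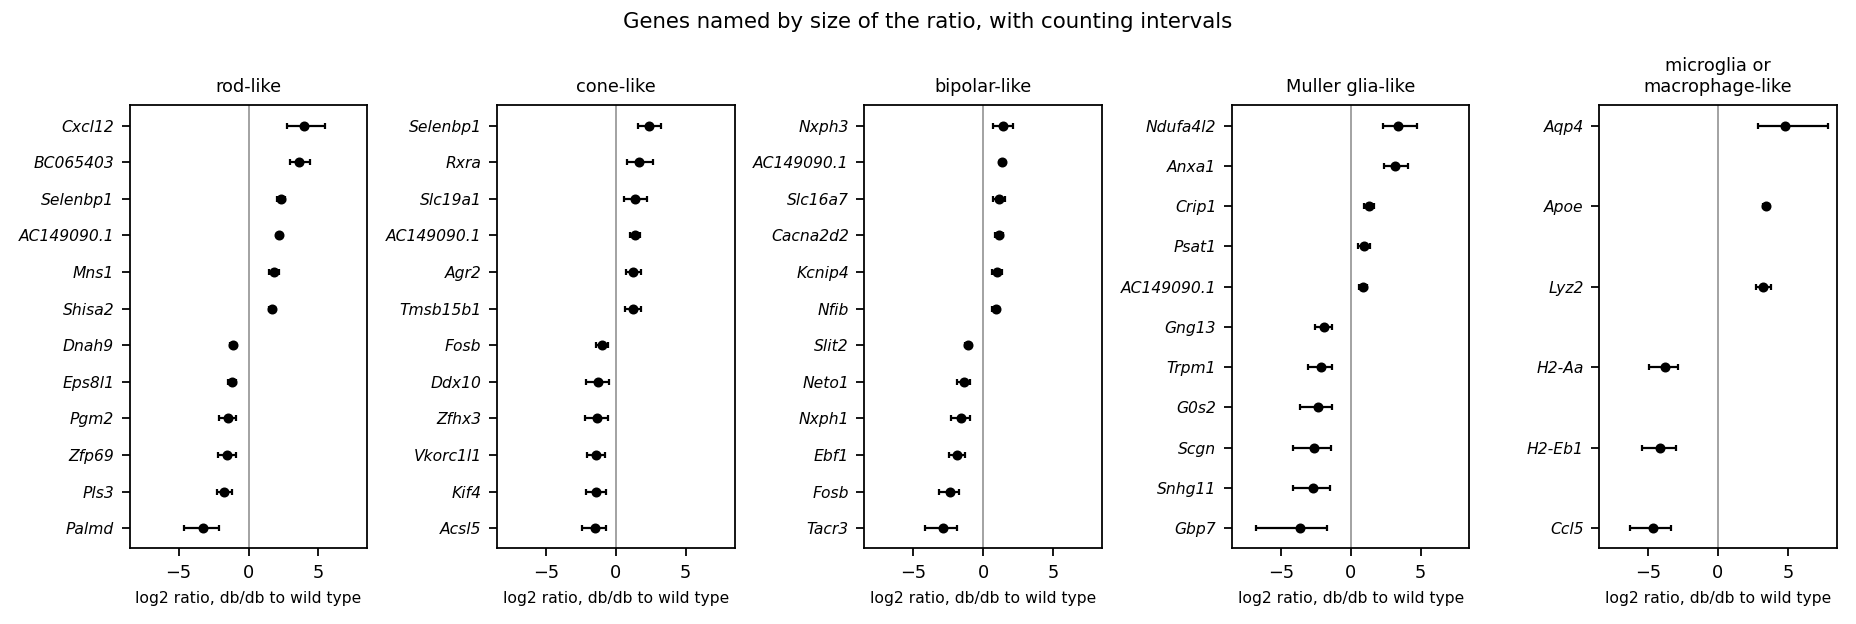
Log2 ratio of db/db to wild type (horizontal axis) of genes named by rule in each compared class, from 1 library per genotype. Points are ratios of CPM from summed UMIs and bars 95% counting intervals; AC149090.1 lies above 0 in rod-like (2.20), cone-like (1.36), bipolar-like (1.32) and Muller glia-like cells (0.88).

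**Figure D3:**
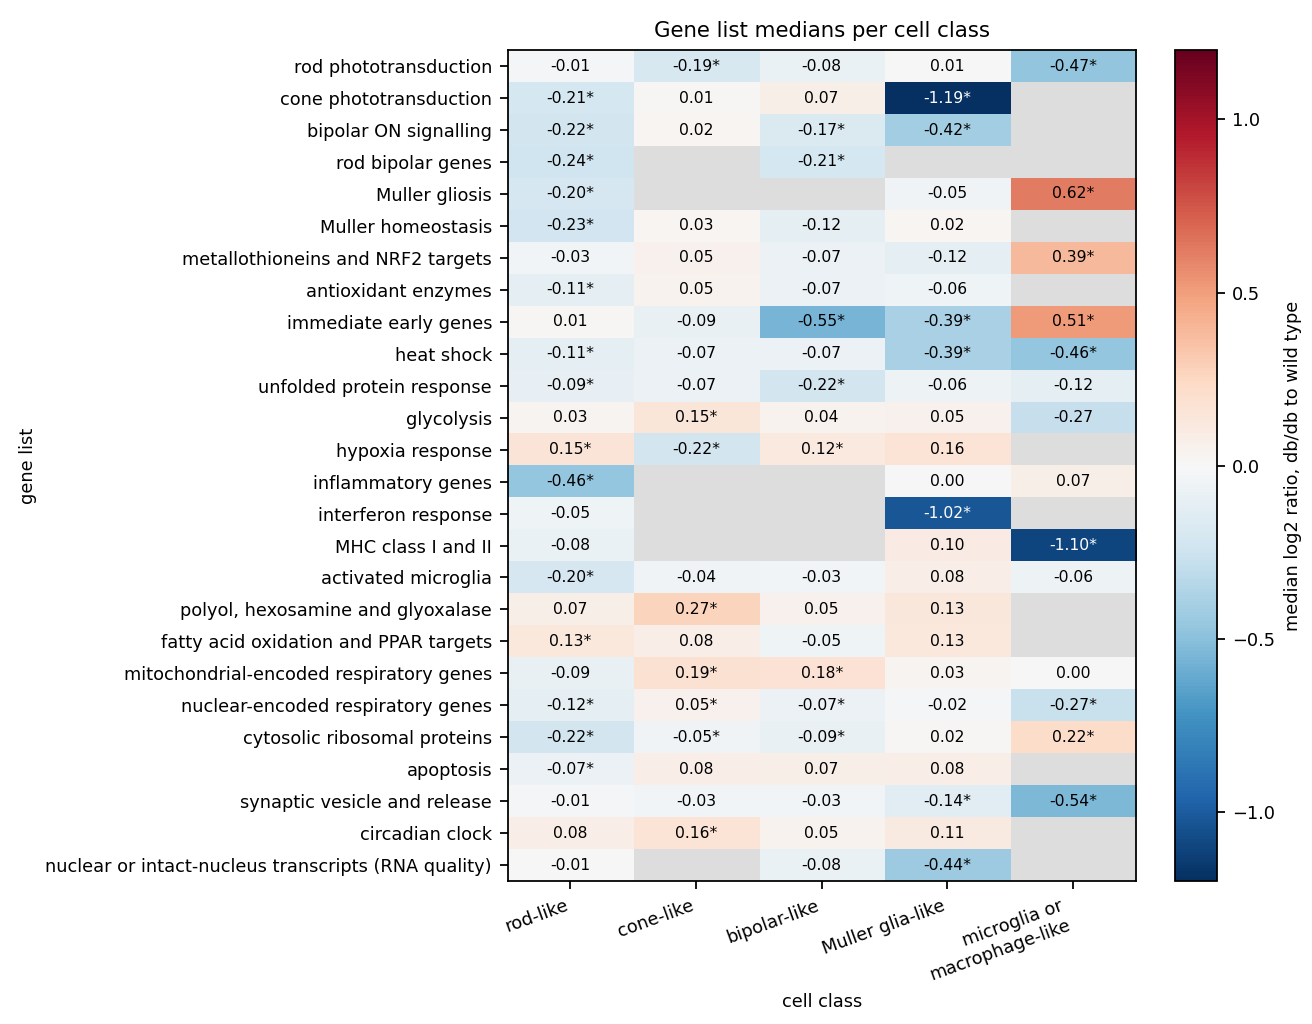
Median log2 ratio of db/db to wild type (colour and printed value) of gene lists (vertical axis) per cell class (horizontal axis), for lists outside the random range in at least 1 class. An asterisk marks medians outside the central 95% of 10000 matched random lists, grey marks lists with under 5 measured members, and immediate early genes are at -0.55 in bipolar-like, -0.39 in Muller glia-like and 0.51 in microglia or macrophage-like cells.

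Across classes, AC149090.1 was the only gene with a log2 ratio of at least 1 in the same direction in at least 4 of the 5 compared classes. Its log2 ratio was 1.15 in microglia or macrophage-like cells and its median over the 5 classes was 1.32. Over all kept cells it was at 48.3 CPM (46.0 to 50.6) in the wild-type and 133 CPM (129 to 137) in the db/db library.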

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

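The tests of a handling difference and of Muller glia RNA were chosen after the result was seen. The other tests of immediate early genes were written down after that pattern was noticed but before their own values were computed, although the interval of the free RNA test was replaced by a directly resampled one after a first value was seen.

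Some gene lists lay outside the random range in opposite directions in different cell classes, which marked them for a closer look. The differences between classes were not tested, because each class has 1 library per genotype. Hypoxia response genes had a median log2 ratio of 0.153 in rod-like cells and 0.1201 in bipolar-like cells of the db/db library, but -0.2236 in cone-like cells. The cone value was -0.0386 after free RNA was subtracted and -0.0521 without the mitochondrial filter, and the bipolar value, whose counting interval includes 0, was 0.0344 without the highest doublet scores. Nuclear-encoded respiratory genes were at -0.1194 in rod-like, -0.0726 in bipolar-like and -0.2673 in microglia or macrophage-like cells, but at 0.0486 in cone-like cells, where the value was 0.00 without the mitochondrial filter. Cytosolic ribosomal proteins were at -0.2211 in rod-like, -0.0454 in cone-like and -0.0889 in bipolar-like cells, but at 0.2209 in microglia or macrophage-like cells, where thinning gave -0.0339. Muller gliosis genes were at -0.1995 in rod-like cells and 0.6202 in microglia or macrophage-like cells. The genes measured in each class differ, and the rod value turned to 0.0967 over genes with at least 200 UMIs.

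Immediate early genes were lower in bipolar-like cells (-0.5545, or -0.3254 among cells with at most 10% mitochondrial UMIs) and Muller glia-like cells (-0.3898) of the db/db library, and higher in microglia or macrophage-like cells (0.5111, from 0.42 to 0.58). RNA-quality transcripts were also lower in Muller glia-like cells (-0.4352). That list holds Snhg11, given above among genes of amacrine or bipolar cells, so its median does not settle whether RNA quality differed. In microglia or macrophage-like cells the median depth was higher in the db/db library. Muller glia RNA was weighed as a source of the higher values in these cells. It was subtracted at the median (6.54%) and highest (30.7%) share that the other Muller markers gave. The median of immediate early genes there was then 0.5568 (0.46 to 0.62) and 0.6387 (0.55 to 0.87), not lower than the 0.5111 without subtraction. At these shares such RNA therefore did not account for the higher values. After thinning alone the median was 0.8131. Doublets may bear on the list as well, but without the 8% of cells with the highest doublet scores the medians were -0.5396 (-0.76 to -0.27) and -0.4577 (-0.51 to -0.42) in bipolar-like and Muller glia-like cells. The doublet caller marked almost no cells, so doublets with low scores may remain and are not excluded. Free RNA stays open, since after its subtraction these medians were -0.7141 (-1.38 to 0.32) and -0.3422 (-0.39 to -0.30). A handling difference also stays open, because the list was at 0.0149 in rod-like and -0.0855 in cone-like cells with members going both ways, and Fosb, chosen here after its values were seen, was at -1.36, -0.98, -2.39 and -0.21 in rod-like, cone-like, bipolar-like and Muller glia-like cells. Genotype stays open and untested.

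Haemoglobin transcripts were not part of any comparison and were marked because they were far above the limit that a count of 0 allows. Hbb-bs was at 1468.749 CPM in the wild-type and 4253.1559 CPM in the db/db library, and Hba-a1 at 576.4254 and 1948.7383 CPM. Of these UMIs, 99.3% in the wild-type and 99.5% in the db/db library lay in erythroid-like cells, of which there were 24 and 40. The remaining cells held 14.5 and 33.4 CPM. The difference between the libraries was not tested, and the amount of blood left in each dissected retina is not known.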

How the results depend on the processing

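The single round of clustering, leaving out 1 bipolar, 1 rod or 1 Muller glia cluster, keeping 1 of the 2 microglia clusters found at a resolution of 2.0, and leaving out members on another chromosome were chosen after the results were seen. No paired analysis was possible because the libraries share only replicate number 1, which does not pair mice, and no test was made.

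Over all alternatives, 809 of 866 values of named genes stayed within their counting interval, 53 moved beyond it and 4 changed direction. For list medians these numbers were 1896, 183 and 8 of 2087, and for share ratios 73, 5 and 1 of 79. Of the gene values, 54 and 22 came from minimums of 20 and 200 UMIs, which cannot change the ratio of a gene. They are counted among the 809. So are 54 values with the 1 called db/db doublet kept and 54 under TMM scaling, settings that alter the counts or totals only slightly. The 10 values of Lepr stayed within their intervals. Thinning moved the most, with 17 of 54 gene values and 43 of 128 list medians beyond their intervals. Thinning also discards UMIs, so its values carry counting error that the intervals of the full counts do not cover. Such moves need not reflect depth. Leaving out the Muller glia cluster led by Abca8a and Trpm3 kept the 12 gene values and 30 list medians of that class within their intervals. Without the rod cluster of low mitochondrial share, the 12 gene values of rod-like cells stayed within their intervals, and 4 of 31 list medians moved beyond them. The share ratio stayed between 1.06 and 1.09 for rod-like and between 0.140 and 0.358 for amacrine-like cells. The lower interferon response in Muller glia-like cells ranged from -1.56 to -1.01, and the log2 ratio of Apoe in microglia or macrophage-like cells from 3.29 to 3.79.

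Among cells that are not rod-like, the share ratio was 1.1782 for cone-like cells, a change of direction, 0.9918 for bipolar-like and 0.6627 for Muller glia-like cells. It was 1.2974 for microglia or macrophage-like cells, also across 1 from 0.889, but both intervals there include 1, so it is not counted as a change of direction. The larger rod share of the db/db library causes this by construction. For the values that follow the cause was not tested, apart from the bipolar cluster, whose own genes are concerned, and the amacrine share.

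Without the 8% highest doublet scores, the Muller glia share ratio was 0.61. Genes of rod phototransduction in cone-like cells were then at 0.0103, and in Muller glia-like cells cone phototransduction genes were at -0.0165 and synaptic vesicle and release genes at 0.1556. In that setting a rod cluster of low UMI count was set apart as mixed with rod. With at least 500 genes per cell the amacrine share ratio was 0.1396, because the cluster of 56 and 18 cells with Snhg11 was then named horizontal and the cluster of 52 and 8 cells led by Gad1 alone counted as amacrine. Without the bipolar cluster led by Slit2, Ntng1 and Neto1, log2 ratios were 0.335 for Ebf1, 1.92 for Nxph1 and 1.1424 for Neto1. Thinned to 1000 UMIs, Psat1 in Muller glia-like cells was at -0.1238, the polyol, hexosamine and glyoxalase list in cone-like cells at 0.4836, cone phototransduction genes in Muller glia-like cells at -0.074 and cytosolic ribosomal proteins in microglia or macrophage-like cells at -0.0339. With free RNA subtracted, rod phototransduction genes in cone-like cells were at 0.0594, cone phototransduction genes in Muller glia-like cells at 1.0146 and immediate early genes in bipolar-like cells at -0.7141. A single round of clustering gave 0.0968 for the polyol list in cone-like cells, and a resolution of 2.0 gave 0.0063 for cytosolic ribosomal proteins there. With at most 10% mitochondrial UMIs, mitochondrial-encoded respiratory genes in bipolar-like cells were at 0.0746. Muller gliosis genes were at 0.0967 in rod-like cells over genes with at least 200 UMIs, and at 1.0695 in microglia or macrophage-like cells over genes with at least 20 UMIs. MHC class I and II genes in the latter were at -0.7934 with at least 20 UMIs, at -0.8136 with equal weight per cell and at -1.5687 with only the deep microglia cluster led by Ccl4 and Ccl3. With only the shallow microglia cluster led by C1qb and Ctss, rod phototransduction genes were at 0.1497, and Ccl5 and Aqp4 had too few UMIs for a ratio.

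The median genes per cell in the wild-type library were 1345.5 with at least 500 genes, 1293 with at most 10% mitochondrial UMIs, 1218 without the highest doublet scores and 693 after thinning, against 1208, 1184, 1113 and 695 in the db/db library. The median UMIs per cell were 2475 and 2152 with at least 500 genes, and 2245.5 and 1968 without the highest doublet scores. Free RNA subtraction moved the median of all genes in microglia or macrophage-like cells to -0.103, from -0.045. Leaving out clusters dominated by 1 library gave no values, since there were none.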

Other observations

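The tests of overlapping genes and of the mix of 2 clusters were chosen or altered after a result was seen, and the other tests were written down after the patterns were noticed but before their own values were computed.

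Microglia or macrophage-like cells of the db/db library had higher Apoe, Lyz2 and Aqp4, and lower Ccl5, H2-Eb1 and H2-Aa. Muller glia RNA may add Apoe, but 12 other Muller markers increased by a median of only 0.0494 (0.0391 to 0.0632) times what the Apoe increase would need, and 132% of the UMIs would have to come from Muller glia. It would lower Lyz2, with a predicted change of -0.1586 (-0.23 to -0.10) times the observed one, whereas for Aqp4, itself a Muller marker, such RNA was not excluded. T or NK cells were weighed as a source of Ccl5, but their markers had 0.0 times the UMIs of Ccl5 (0 to 0.0376) in the wild-type class. With equal weight per cell the median log2 ratio of the 6 genes in their own direction was 1.8134. This argues against the depth of a few cells as the whole cause, but a few cells rich in a gene keep their effect under equal weight. The cells that carried each gene were not counted, so such cells stay open. At a resolution of 2.0 the class split into a deep cluster of 33 wild-type and 37 db/db cells and a shallow one of 29 and 23, but from summed UMIs the median in their own direction was 4.7271 (4.01 to 5.23) over the 6 genes in the former and 2.5657 (2.0 to 3.44) over 4 of them in the latter, against a different mix of these clusters as the whole cause. Ccl5 and Aqp4 had at most 3 UMIs in the shallow cluster and so no ratio there. B cells as a source of MHC class II RNA, finer mixes of microglia and macrophages, and an effect of genotype stay open and untested.

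BC065403 and Mns1, both higher in rod-like cells of the db/db library, lie close together on chromosome 9. Their annotations are 28065 bases apart, which argues against reads shared by overlapping genes. Stretches of the genome that differ between the mice of the libraries may contribute. Of the genes with a log2 ratio of at least 1 in size, 17.9% had another of the same direction within 1 Mb, at percentile 99.02 of 10000 shuffles with a median of 7.37%, and without these 2 genes the share was 16.1% at percentile 98.0. Haemoglobin genes were not left out of this count, unlike in the naming rule. Hbb-bs was at 10.3 CPM in wild-type and 21.9 CPM in db/db rod-like cells. Such genes may add to the share, so it does not decide whether stretches of the genome contribute. Neighbouring genes can also share regulation, and no sequence variants were examined, so genotype at the Lepr locus and other strain differences stay open.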
